A study of Mus musculus with 29 samples.

How the data were processed

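RNA from 29 cultures of mouse lung adenocarcinoma cells was hybridised to Affymetrix mouse exon arrays. Per the labels' protocols, RNA was extracted with Trizol, and targets were made with the Affymetrix WT Sense kit on 27 arrays and with the NuGEN Ovation kit on 2. The deposited values are on a log2 scale, 1 per transcript cluster and array, and the submitters' processing notes name RMA and Partek 6.5, without saying in what order they were used. The background step, the summarisation settings and the genome build are not given in the sources used here. A deposited list that groups exon probe sets into the same 44343 clusters gave the number of probes per cluster (median 12). No scanner values were analysed here, so signal over background is not known per cluster. The deposited arrays do not share a common distribution, with medians of 4.42 to 4.94 for the WT kit and 5.57 and 5.59 for the Ovation kit, so shifts between whole arrays enter the differences and were addressed by the alternative normalisations.

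Gene names came from the platform annotation, checked by Entrez number against a table of mouse genes of assembly GRCm38.p6. A single gene was named for 22781 clusters, several for 2085 and none for 19477. A gene with several clusters was represented by the one with the highest mean over all arrays, which left 18997 genes, and 2076 genes had more than 1 cluster. The Entrez numbers of 296 clusters were not in that table and kept their platform symbol. Nkx2-1 has only a cluster that it shares with Sfta3-ps, so it takes no part in tests of named genes and gene lists.

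Groups came from the labels: 14 primary lines, 9 metastasis lines, 3 control arrays and 3 arrays with the hairpin against Nkx2-1. The protocol also names a class TnonMet, which the labels do not give per line. The primary lines were therefore kept as a single group, which may hold lines of more than a single class. Nothing in the labels says that lines were cultured more than once, so p-values measure the spread between lines, and for 394T4 between labelling kits. The pairing of the infected arrays comes from the labels, which put a control beside each hairpin array of the same line and kit; deviations from the group means correlated within the 3 pairs at 0.685, 0.638 and 0.936. The labels do not say whether both 394T4 pairs used the same RNA. Runs of consecutive array numbers were read from the labels and used as batches.

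The design, gene lists, rule for named genes and most of the alternatives were fixed before the data were examined. Metastasis and primary lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 44343 clusters, threshold 0.05), with no covariate. Hairpin and control arrays were compared in the same way over 6 arrays with the pair as a block. The 19 lists (409 of 460 genes measured) cover lung epithelial differentiation, foregut and gut endoderm, oncofetal genes, epithelial junctions, mesenchymal genes, matrix remodelling, cell cycle, p53 targets, interferon response, antigen presentation, hypoxia and glycolysis, TGF-beta and Wnt signalling, RAS and MAPK feedback, and markers of leukocytes, endothelium, fibroblasts, hepatocytes, kidney epithelium and mesothelium. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, and their members were also adjusted over the list alone. Single levels were compared by exact permutation of the difference of means over all splits, and correlations by 100000 resamples, or exactly for fewer than 10 lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

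Named genes are Nkx2-1 and Hmga2, then in each comparison the 8 genes with the largest positive and the 8 with the largest negative difference among those past the threshold, or those with the smallest p where fewer passed, and up to 4 members of each list with the smallest p. The text prints only part of the list members the rule allows, and that part was picked after their values were seen; exceptions to the rule are said where they stand. Copies within gene families are marked as uncertain.

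The fits were tested on simulated data for 44343 clusters, of which 200 were changed. With noise drawn from each cluster's residual SD, limma called 14.9%, 77.6% and 100% of clusters changed by 0.5, 1 and 2 in the layout of 23 lines. In the layout of 3 pairs the same noise gave 0 calls at every size. The noise for the pairs was then drawn from limma's moderated SDs, a choice made after that result, because a residual SD from 3 pairs is itself poorly estimated. This gave 0%, 25.4% and 93.9% for the pairs, and 13.4%, 82.1% and 100% for the lines. The recovery to be counted on from 3 pairs therefore depends on how the spread is modelled. Estimates had the simulated sign in all changed clusters of the pairs, and for the lines in 95.5% at 0.5 and in all at 1 and 2. Of the unchanged clusters 12 were called for the lines under either noise, and for the pairs 0 with residual and 9 with moderated SDs. Changed clusters were drawn at random from all 44343, with the same SD in both groups and independent lines. Recovery may be lower for genes with a large or unequal spread, such as Nkx2-1 (SD 1.76 and 0.09).

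Alternatives were another normalisation (quantile again, or centring on the median), leaving out the dimmest 33.3% of clusters, eBayes with trend and robust, blocks for array run and line number, all 29 arrays in the fit, a minimum difference of 1, averaging the 394T4 kits, and leaving out each pair or the lines of each number. Alternatives added after the data were seen were leaving out line 389T5, line 482N1, or lines 482N1, 389T2 and 393T5, a permutation test of list means per line, blocks for the Nkx2-1 level, the members of each list under the alternatives of the infected arrays, and the settings of run, normalisation, pair block and left-out lines for gene lists. Nothing was left out of the main fits.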

Results

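Transcript levels were measured on 29 mouse exon arrays hybridised with RNA from cultured lung adenocarcinoma cells that carry activated Kras and lack p53. The tumours had been started in mice by a lentivirus carrying Cre recombinase, and each line was grown from a single lung tumour or metastasis. Lines from primary lung tumours numbered 14. The 9 lines from metastases comprised 5 from lymph nodes, 2 from the liver, 1 from the kidney and 1 from pleural fluid. A further 6 arrays held cells of lines 394T4 and 368T1 infected with a control vector (n = 3) or with a short hairpin RNA against Nkx2-1 (n = 3), a homeobox transcription factor that maintains lung epithelial identity. Each array gave a log2 value for 44343 transcript clusters, of which 22781 were annotated to a single gene. Array medians lay between 4.42 and 4.94 for the 27 arrays labelled with the WT kit, and at 5.57 and 5.59 for the 2 labelled with the Ovation kit. The number of arrays limits the precision of every difference. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed.

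The first comparison asked how lines from metastases differ from lines from primary tumours, and whether Nkx2-1 differs between them. Nkx2-1 was read by transcript cluster 6800974 (78 probes), which is annotated both to Nkx2-1 and to its neighbour Sfta3-ps, so the signals of these genes cannot be separated. The cluster averaged 5.13 ± 1.76 (SD, n = 14) in primary lines and 3.81 ± 0.09 (SD, n = 9) in metastasis lines, a difference of -1.32 (two-sided exact permutation test over 817190 splits, p = 0.0202). The lines fell on either side of a gap between 5.00 and 6.77. Above it were the primary lines 802T4 (8.48), 393T1 (8.12), 368T1 (7.48) and 2557T1 (6.77), and below it were the other 10 primary lines and all 9 metastasis lines. The array numbers in the labels form 4 runs, each with lines of both groups, and within these runs the difference was -0.12, -1.91, -1.13 and -2.64. Run 3 holds a single metastasis line, 389N1, against 7 primary lines, so every shift within run 3 given here and below rests on that line. With the run as a block the Nkx2-1 difference was -1.57. With the line number as a block, over the 17 lines of the 4 numbers found in both groups, it was -0.72 (limma, unadjusted p = 0.132). In limma's fit across all clusters the adjusted p was 0.836. The exact p rose above 0.05 when the lines of 1 number were left out, which gave -1.15 (p = 0.0582) without the 393 lines, -1.19 (p = 0.0534) without 2557T1, -1.14 (p = 0.0505) without 368T1 and -1.33 (p = 0.0502) without the 2691 lines.

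**Figure D1:**
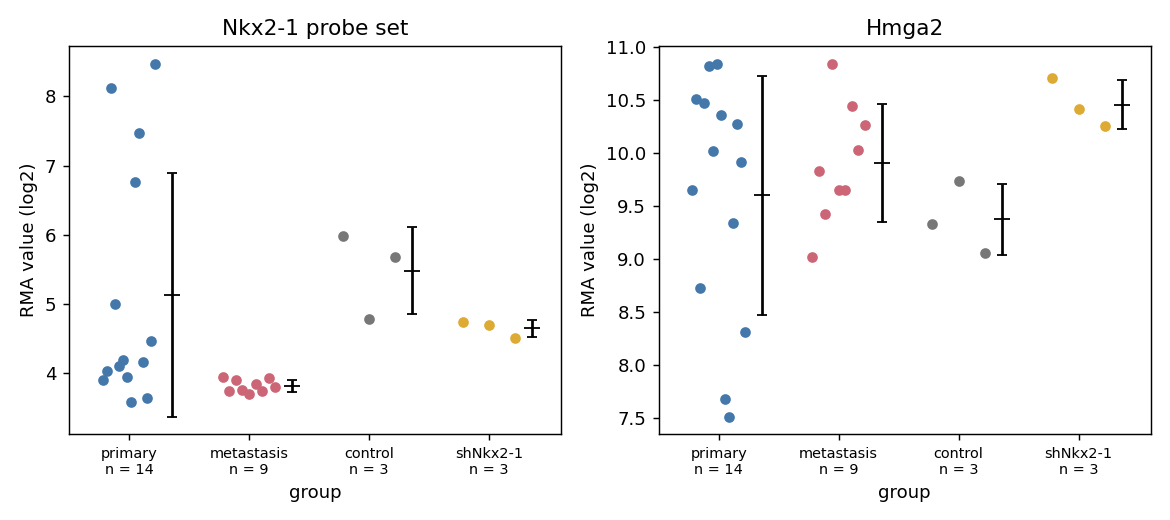
RMA values (log2) of the Nkx2-1/Sfta3-ps probe set and of Hmga2 on each array, by group; points are arrays, the horizontal mark is the group mean and the bar is 1 SD. In the left panel 4 primary lines lie at 6.77 or above, and all 9 metastasis lines lie below the gap that starts at 5.00.

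Hmga2, an embryonic chromatin protein that the study followed (cluster 6777518), averaged 9.60 ± 1.13 (SD, n = 14) in primary lines and 9.91 ± 0.55 (SD, n = 9) in metastasis lines, a difference of 0.30 that did not pass the exact permutation test (p = 0.463). Within the 4 runs it was -0.66, 0.12, 0.22 and 0.99, and with the run as a block 0.23, but with the line number as a block it turned to -0.28. Because of the gap in the Nkx2-1 levels no correlation was computed over all 23 lines, and the 4 lines above the gap were too few for one. Their Hmga2 values were 8.31 in 802T4, 8.73 in 393T1, 7.51 in 368T1 and 7.68 in 2557T1, while the 19 lines below the gap ranged from 9.02 to 10.85. All 4 thus lay below every line under the gap. The gap was found in the Nkx2-1 values alone, without those of Hmga2. No test of this difference was set down beforehand, and none was run. In the 19 lines below the gap no relation of the Nkx2-1 and Hmga2 values was found (Pearson r = 0.05, permutation p = 0.856, and Spearman rho = 0, p = 1), nor without the 2 lines farthest from the median (r = -0.13, p = 0.612). In the 9 metastasis lines r was -0.54 (exact permutation p = 0.133) and rho was -0.50 (exact permutation p = 0.178), and r was -0.43 without the 2 farthest lines (exact permutation p = 0.329). In the 10 primary lines below the gap r was -0.03 (permutation p = 0.931) and rho was -0.13 (p = 0.732). These 5 relations had adjusted p-values from 0.664 to 0.931. The Nkx2-1 values below the gap lay at 3.58 to 5.00, mostly under the array medians of 4.42 to 4.94. At so low a signal these correlations cannot decide whether the levels are related among the lines below the gap.

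Genes with the smallest p-values in the comparison of metastasis with primary lines are named here as values, since none passed the threshold (each had an adjusted p of 0.836 in limma). Higher in metastasis lines were Abcg1, a cholesterol efflux transporter, by 1.59 ± 0.35 (SE), Il1rl2, the interleukin-36 receptor, by 0.94, Tsc1, an inhibitor of mTORC1 signalling, by 0.51, and Ttf1, a termination factor of ribosomal RNA transcription unrelated to Nkx2-1 despite the shared name, by 0.57. Rabl6 (0.43), Bcorl1 (0.43), Ptpra (0.44) and Ap5s1 (0.57) completed the group. Lower in metastasis lines were the sodium bicarbonate cotransporter Slc4a4 at -1.77 ± 0.49 (SE), the cell-surface mucin Muc1 at -1.73, Dram1, which acts in autophagy, at -1.70, the transcriptional regulator Prdm16 (4 probes) at -1.42 and the phospholipid flippase Atp8a1 at -1.33. Ly6i (-0.99), Jakmip2 (-0.35) and Ang4 (-0.33) were the others, and Ly6i and Ang4 belong to families of close copies that probes may not separate. In the metastasis lines Prdm16 (3.49 to 4.41), Jakmip2 (3.99 to 4.45) and Ang4 (3.09 to 3.68) had low signal, near or under the array medians of 4.42 to 4.94. With the run as a block all 16 genes had the same direction, and 15 had it within each of the 4 runs, the exception being Ang4. They were picked for small p-values in these same lines, so this agreement follows largely from the choice and is no support. At an adjusted p under 0.05 limma called 0 of the 44343 clusters, the smallest adjusted p being 0.836. At an unadjusted p under 0.05 it found 2523 (773 higher and 1750 lower), where 2217 were to be counted by chance. That split turned with the scaling, to 2141 higher and 884 lower after centring each array on its median, and to 1532 and 1135 after quantile normalisation.

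Of the 19 gene lists fixed beforehand, the list of lung epithelial differentiation was lower in metastasis lines, with a mean shift of -0.52 over 35 measured genes, 32 of them lower (camera, adjusted p = 3.9e-08; adjusted p = 0.168 with an estimated correlation). Its within-run shifts were -0.19, -0.62, -0.35 and -1.04. The shift was -0.60 with the run as a block and -0.34 with the line number as a block (adjusted p = 0.000325, and 0.790 with an estimated correlation). The highest list means were those of the primary lines 802T4 (6.87), 393T1 (6.55) and 368T1 (6.31), which also lay above the Nkx2-1 gap. In 2557T1, the other line above it, the list mean was 5.99. The shift without these lines together was not computed. Adjusted over the list alone 2 genes passed, Dram1 and Muc1 (both 0.0412), and over all genes 0 passed. The surfactant protein gene Sftpb stood at -1.93 ± 0.63 (SE) and the alveolar claudin Cldn18 at -2.77 ± 0.92 (SE). The epithelial junction list was also lower, at -0.55 with 33 of 37 genes lower (camera, adjusted p = 1.0e-08; adjusted p = 0.562 with an estimated correlation), and within runs at -0.31, -0.84, -0.09 and -0.57. With blocks it was -0.49 for the run and -0.32 for the line number (adjusted p = 0.00501, and 0.790 with an estimated correlation). Among its members were the epithelial transcription factors Ovol2 (-0.26) and Ehf (-1.84), the sorting adaptor Ap1m2 (-0.86) and the membrane protease St14 (-1.12), with 0 genes passing over all genes or over the list alone. In the metastasis lines Ovol2 (4.05 to 4.47) and Ap1m2 (3.95 to 4.17) had low signal, near or under the array medians of 4.42 to 4.94.

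The mesenchymal list was higher in metastasis lines, at 0.53 with 32 of 34 genes higher (camera, adjusted p = 1.7e-06; adjusted p = 0.562 with an estimated correlation). Its shift was -0.36, -0.09, 1.22 and 1.30 within the 4 runs and 0.53 with the run as a block. Named members were the transcription factors Snai1 (0.88) and Prrx1 (1.37) and the collagen genes Col6a2 (1.10) and Col6a1 (1.04), none of them past the threshold over all genes or over the list alone. The fibroblast marker list moved with it, at 0.48 with 16 of 17 genes higher (camera, adjusted p = 0.00430; adjusted p = 0.562 with an estimated correlation), including Col3a1 (1.04) and Postn (1.47); it shares 10 of its 17 genes with the mesenchymal list. Its within-run shifts were -0.29, -0.03, 1.04 and 1.16, and 0.48 with the run as a block, and its call was lost after centring each array on its median (0.56, adjusted p = 0.0790). Lymph node line 482N1 had the highest fibroblast marker mean, 8.25 against 4.76 to 6.16 in the other 8 metastasis lines. Without it the fibroblast shift was 0.16 (adjusted p = 0.562) and the mesenchymal shift 0.30 (adjusted p = 0.0156). Without it and the primary lines 389T2 and 393T5 these shifts were 0.43 (adjusted p = 0.000593) and 0.55 (adjusted p = 9.4e-08). Lines 389T2 and 393T5 had the highest fibroblast marker means of the primary lines, 7.05 and 6.64. Leaving them out lowers the primary mean of that list and so raises its shift by construction. The mesenchymal list shares 10 genes with it. The p-values of this setting therefore decide nothing about either shift. Without all lines of number 482 the fibroblast and mesenchymal shifts were 0.12 (adjusted p = 0.811) and 0.26 (adjusted p = 0.149).

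**Figure D2:**
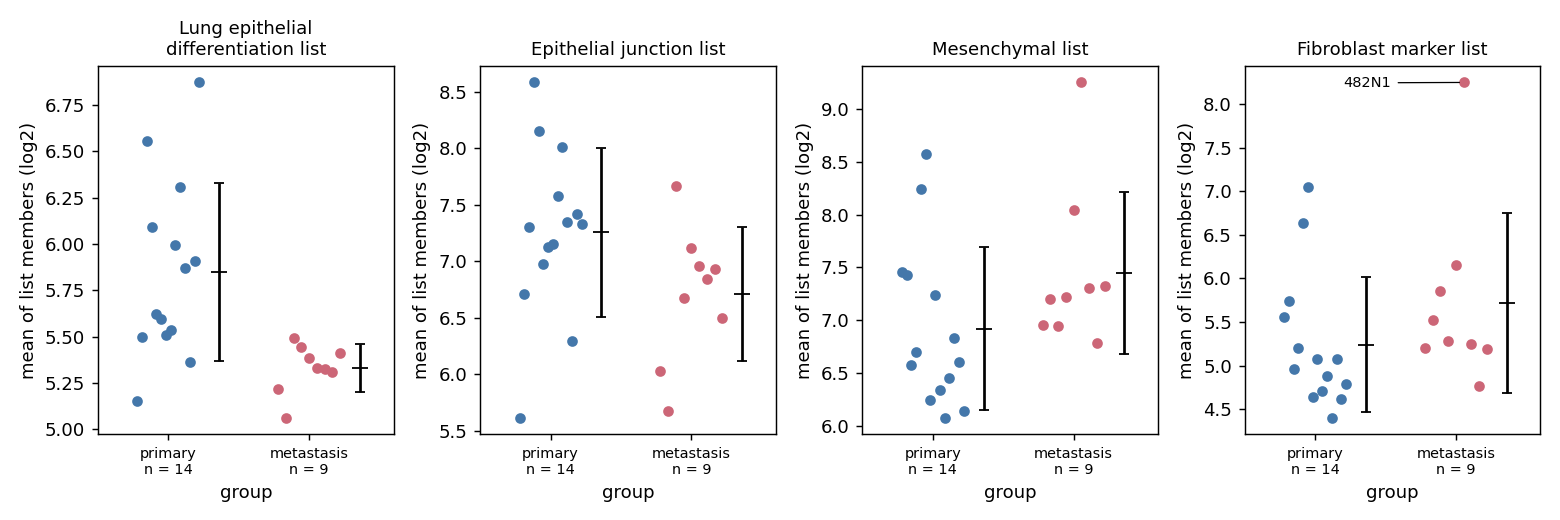
Mean log2 value of the measured members of 4 gene lists in each primary (n = 14) and metastasis (n = 9) line; points are lines, the horizontal mark is the group mean and the bar is 1 SD. Metastasis lines average 5.33 against 5.85 for the lung epithelial list, and line 482N1 stands at 8.25 for the fibroblast marker list.

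The interferon response list was lower in metastasis lines, at -0.30 with 23 of 23 genes lower (camera, adjusted p = 4.3e-05; adjusted p = 0.562 with an estimated correlation), among them the RNA sensors Ifih1 (-0.91) and Ddx58 (-0.54). Its shift was -0.08, -0.49, -0.13 and -0.98 within runs and -0.48 with the run as a block. With the line number as a block it was -0.15 (adjusted p = 0.00729, and 0.790 with an estimated correlation). The primary line 802T4 had the highest interferon mean, 6.72, and also the highest leukocyte marker mean, 6.25, and without it the interferon shift was -0.17 (adjusted p = 0.00827). The foregut and gut endoderm list stood at -0.19 with 23 of 33 genes lower, including Gata6 (-1.18), at an adjusted p of 0.0416 by camera (adjusted p = 0.572 with an estimated correlation). This call was lost with the run as a block (-0.06, adjusted p = 0.686), with the line number as a block (mean 0.05, adjusted p = 0.987) and without 368T1 (-0.12, adjusted p = 0.139), 404T1 (-0.15, adjusted p = 0.122), 389T5 (-0.16, adjusted p = 0.0672) or the 373 lines (-0.06, adjusted p = 0.456), while without the 393 lines the shift was -0.35. Its within-run shifts were -0.45, 0.36, 0.03 and -0.18. The 13 other lists did not pass in this fit. With the run as a block 5 of them did, matrix remodelling (0.27, adjusted p = 0.0423), the cell cycle (-0.23, adjusted p = 0.0263), antigen presentation (-0.24, adjusted p = 0.0151), TGF-beta and Wnt signalling (0.25, adjusted p = 0.0245) and leukocyte markers (-0.18, adjusted p = 0.0324). None of the 5 had the same sign within all 4 runs. An estimated correlation was not used with this block, and with no block it gave camera adjusted p-values of 0.572 to 0.715 for these lists. Shifts within runs were -0.28, -0.20, 1.24 and 0.48 for matrix remodelling, -0.19, -0.82, -0.40 and 0.39 for the cell cycle, -0.04, -0.18, 0.02 and -0.62 for antigen presentation, -0.19, -0.05, 1.14 and 0.27 for TGF-beta and Wnt signalling, and 0.18, 0.01, 0.27 and -0.92 for leukocyte markers. Without 802T4, which is 1 of the 2 primary lines of run 4, and with no block, antigen presentation stood at -0.07 (adjusted p = 0.647) and leukocyte markers at 0.07 (adjusted p = 0.702). The cell cycle list passed in 10 of its 17 alternatives, among them both other normalisations, but its shift turned to 0.0391 without the 393 lines (adjusted p = 0.311). Mean shifts were 0.24 for matrix remodelling, -0.15 for the cell cycle (Ccnb2, -0.48), 0.04 for p53 targets, -0.16 for antigen presentation, 0.01 for hypoxia and glycolysis, 0.14 for TGF-beta and Wnt signalling, and -0.16 for hepatocyte, -0.06 for leukocyte, -0.01 for endothelial, -0.04 for kidney epithelial and -0.18 for mesothelial markers. The oncofetal list had a positive mean (0.04) and the RAS and MAPK feedback list a positive median (0.05) with a negative mean (-0.08), while camera's direction was down for both. When each line's list mean was compared by an exact permutation test over 817190 splits, a test added after the values were seen, 0 of the 19 lists had an adjusted p under 0.05 and 1 had an unadjusted p under 0.05, lung epithelial differentiation (p = 0.00386, adjusted p = 0.0734).

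The second comparison asked which genes differ between the arrays labelled shNkx2-1 and their controls. In the 394T4 pairs the Nkx2-1/Sfta3-ps probe set read 5.99 with the control vector and 4.75 with the hairpin under the WT kit, and 5.68 and 4.50 under the Ovation kit. In the 368T1 pair it read 4.78 and 4.69, so that the array labelled shNkx2-1 was nearly level with its control and the target does not check the labels of this pair. Differences shared by all 3 pairs therefore cannot be assigned to a lower Nkx2-1 level. The differences were -1.24, -1.18 and -0.10, with a mean of -0.84 ± 0.64 (SD, n = 3 pairs). With the 394T4 kits averaged, so that each line counted once, the mean was -0.65 (limma, unadjusted p = 0.111). An exact sign-flip permutation test of 3 pairs cannot go below p = 0.25, which was its value. Hmga2 was higher in each array labelled shNkx2-1, by 1.38 and 1.19 in 394T4 and by 0.68 in 368T1 (mean 1.08 ± 0.18, SE).

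Genes with the smallest p-values in this comparison, none past the threshold over all clusters, moved the same way in all 3 pairs. Their choice by p nearly fixes this, since 99.4% of genes at an unadjusted p under 0.05 had the same sign in all pairs. Higher in the arrays labelled shNkx2-1 were the centriole protein gene Cntln (4 probes) by 2.23 ± 0.14 (SE), the coagulation inhibitor Tfpi by 2.17, Dpysl3 and Uchl1, best known from neurons, by 2.16 and 1.81, the zinc-finger gene Zfp820 (4 probes) by 1.86, Adgrg2 by 1.60, the complement-activating protease Masp1 by 1.45 and the adhesion molecule Ncam1 by 1.30. Lower were Emb, an adhesion protein, at -2.71 ± 0.30 (SE), the protease Tmprss11e at -2.07, Arap2 at -2.00, the palmitoyltransferase Zdhhc15 at -1.85, Rasef at -1.72, the magnesium transporter Mmgt1 at -1.51, the tubulin Tuba8 at -1.46 and the sterol-pathway enzyme Idi1 at -1.38. Their adjusted p-values lay at 0.399 to 0.406. Limma, with the pair as a block, called 0 of the 44343 clusters, against 4077 at an unadjusted p under 0.05 (1951 higher and 2126 lower). That split also turned with the scaling, to 2374 higher and 1675 lower after centring each array on its median, and to 2190 and 1779 after quantile normalisation. With all 29 arrays in the fit it called 3 higher and 5 lower clusters. The named ones, chosen after their values were seen, were Kdsr (1.03, adjusted p = 0.0468), 4930435H24Rik (1.42, adjusted p = 0.00688), Lmbrd2 (-1.47, adjusted p = 0.0188) and Gbe1 (-2.29, adjusted p = 0.0218).

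**Figure D3:**
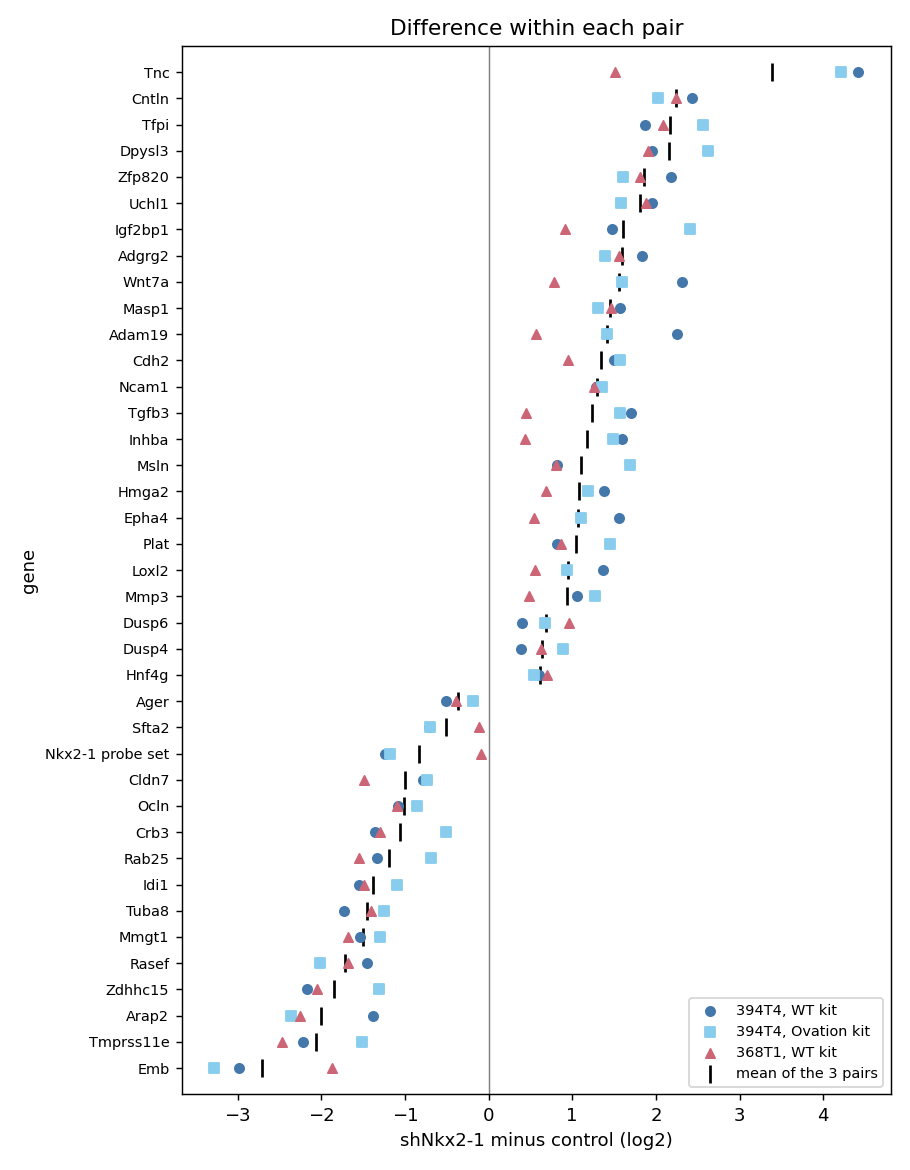
Difference (log2) between the array labelled shNkx2-1 and its control within each of the 3 pairs, for the genes named in the text and the Nkx2-1/Sfta3-ps probe set; symbols are pairs and the black mark is their mean. For the probe set the 394T4 pairs lie at -1.24 and -1.18 and the 368T1 pair at -0.10, while Cntln lies above 2 in all 3 pairs.

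Of the 19 lists 4 passed camera in the knockdown comparison, and none did with an estimated correlation. The epithelial junction list was lower at -0.35, with 27 of 37 genes lower (adjusted p = 0.00484; adjusted p = 0.671 with an estimated correlation). Adjusted over the list alone 5 junction genes fell, the tight junction genes Ocln (-1.01), Cldn7 (-0.78, -1.49 and -0.73 in the pairs) and Crb3 (-1.06), the trafficking GTPase Rab25 (-1.19) and the epithelial transcription factor Elf3 (-1.14, chosen after its value was seen), and 0 passed over all genes. With the kits of 394T4 averaged 4 of them passed, and Cldn7 did not (adjusted p = 0.0521). All 5 passed after median centring, but none after quantile normalisation (adjusted p = 0.0711 over the list alone) or with trend and robust (0.0515). None passed without the 394T4 WT pair (0.195) or without the 368T1 pair (0.0901 to 0.112). This list's shift was -0.76 in 368T1 but -0.27 and -0.01 in 394T4, and without the 368T1 pair it was -0.14 (adjusted p = 0.273). Without the pair block its adjusted p was 0.192. The matrix remodelling list was higher at 0.26, with 21 of 28 genes higher (adjusted p = 0.00145; adjusted p = 0.671 with an estimated correlation). Over the list alone 6 of its genes rose, among them the plasminogen activator Plat (1.04), the collagen cross-linking enzyme Loxl2 (0.95) and the metalloproteinases Mmp3 (0.94) and Adam19 (1.41), each with an adjusted p of 0.0499. With the 394T4 kits averaged, so that each line counted once, none of these 6 passed (adjusted p = 0.134 to 0.182 over the list alone). The TGF-beta and Wnt list was higher at 0.29, with 17 of 28 genes higher (adjusted p = 0.00484; adjusted p = 0.671 with an estimated correlation), with the ligand genes Wnt7a (1.56), Inhba (1.17) and Tgfb3 (1.24). The RAS and MAPK feedback list was higher at 0.23, with 17 of 21 genes higher (adjusted p = 0.00145; adjusted p = 0.671 with an estimated correlation), with the ephrin receptor Epha4 (1.07) and the MAP kinase phosphatases Dusp6 (0.68) and Dusp4 (0.64). None of these 6 signalling genes passed over the list alone, and without the 394T4 Ovation pair the RAS and MAPK shift was 0.13 (adjusted p = 0.0908).

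The 15 other lists did not pass camera in the infected arrays. Lung epithelial differentiation stood at -0.05, with 24 of 35 genes lower, including Sfta2 (-0.51) and Ager (-0.36), of which 0 passed. Over their lists alone Hmga2 and the RNA-binding protein gene Igf2bp1 (1.60) rose in the oncofetal list (both adjusted p = 0.0341), N-cadherin, Cdh2, rose by 1.34 in the mesenchymal list (adjusted p = 0.0262) and Msln rose by 1.11 among the mesothelial markers (adjusted p = 0.0473). With the kits averaged none of these passed, at 0.0935 for Hmga2 and Igf2bp1, 0.150 for Cdh2 and 0.0555 for Msln. Of the 15 genes called over a list alone in all lists 4 passed with the kits averaged, and 0 without the 394T4 WT pair, without the pair block or with all 29 arrays in the fit. After median centring 15 passed, after quantile normalisation 5 and with trend and robust 10. Without the 368T1 pair 9 passed, and without the 394T4 Ovation pair 4. Tenascin C, Tnc, differed by 3.38 ± 0.62 (SE) without passing (0.0567 over the list alone). The oncofetal list had a mean of 0.16 with a median of -0.04 and the mesenchymal list a mean of 0.23 with a median of -0.05, and camera's direction was up for both. Shifts of the remaining lists were -0.08 for foregut and gut endoderm (Hnf4g, 0.61; -0.31 and an adjusted p of 0.0197 without the 368T1 pair), 0.00 for the cell cycle, -0.02 for p53 targets, -0.11 for interferon response, -0.20 for antigen presentation and 0.01 for hypoxia. Among cell type markers they were -0.10 for leukocytes, -0.08 for endothelium, -0.02 for fibroblasts, -0.17 for hepatocytes (-0.18 and an adjusted p of 0.0347 without the 394T4 WT pair), -0.01 for kidney epithelium and 0.13 for mesothelium.

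The responses of the pairs were set side by side, without a test. Across 18997 genes, which are not independent replicates, the differences of the 394T4 pairs made with the WT and Ovation kits correlated at r = 0.59, and those of 368T1 correlated with them at 0.07 and 0.18. All 3 pairs had the same sign for 36.4% of genes. Independent signs would give 25%, but the 394T4 pairs are the same line and correlate with each other. The excess over 25% therefore cannot be read as agreement between lines. In all 3 pairs 31 genes were at least 1 higher and 14 at least 1 lower in the array labelled shNkx2-1.

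The last comparison asked whether genes that respond to the hairpin also differ between metastasis and primary lines. Since no gene passed in the infected arrays, the 100 genes per direction with the smallest p and the same sign in all pairs were taken, as laid down beforehand. Of the 100 genes lower in the arrays labelled shNkx2-1 52 were lower in metastasis lines (mean shift -0.11), and of the 100 higher in them 45 were higher in metastasis lines (mean shift -0.10). Neither set passed camera (both adjusted p = 0.486; both adjusted p = 0.579 with an estimated correlation). Across 18997 genes the differences of the comparisons correlated at r = 0.04 (Spearman 0.06). At an unadjusted p under 0.05 in both there were 128 genes against 85.3 for independent lists, 78 of them with the same sign, and 0 genes passed limma's threshold in both.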

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

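In this part the tests of equally treated cells, of exchanged arrays or labels, of a low control level, of array batches, of shifts within runs without number 482 and of splits by unadjusted p were chosen only after the result was seen, as were the settings that leave out line 482N1; the others were set down beforehand. The test of equally treated cells replaced an earlier measure, also used for exchanged labels: the share of genes past 1 in both 394T4 pairs that kept their sign in 368T1, which was 81.6% for higher and 41.3% for lower genes.

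Values far from the other metastasis lines were looked for in 53 sets of 9 lines, and 5 were found where chance gives 2.65, about 1 in 20. The gap to the nearest line as a share of the whole range was 0.526 for Ap5s1 and 0.521 for St14 (both line 393n1), 0.505 for the hypoxia and glycolysis list mean (373b1), 0.596 for the RAS and MAPK feedback list mean (393n1) and 0.600 for the fibroblast marker list mean (482N1). Between hairpin and control arrays the foregut and gut endoderm list moved by 0.39 in 368T1 and by -0.29 and -0.34 in 394T4, a difference between lines that was not tested. The interferon response list moved by 0.0426 in 368T1 and by -0.17 and -0.21 in 394T4, likewise not tested.

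For the calls among the 44343 clusters in metastasis against primary lines the splits decide nothing, because the real split had 0 calls, which all 100 splits reach, and the highest other had 57. At an unadjusted p under 0.05 chance cannot be excluded, since the real split had 2523 clusters, 30 of the 100 splits had as many and the highest other had 6966. So high a count may come from a structure of the lines other than their origin, which was not tested. For the gene lists chance cannot be excluded either: 51 of the 100 splits had at least the 6 lists of the real one, and the highest other had 12. The 6 infected arrays allow 10 splits into 3 and 3, too few for a share under 0.05. There the real split had 0 clusters (highest other 0), 4077 at an unadjusted p under 0.05 (highest other 2742) and 4 lists (highest other 8, and 2 among the other splits that part all pairs).

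The Nkx2-1/Sfta3-ps probe set was nearly level in the 368T1 pair (-0.10, against -1.24 and -1.18 in 394T4). An exchange of a 368T1 with a 394T4 array is argued against by Xist, whose lowest value in the 394T4 arrays lay 7.41 above its highest in the infected 368T1 arrays. For equally treated 368T1 cells the higher and the lower genes gave different pictures. Of those at least 1 higher in both 394T4 pairs, 31 were so in 368T1 (3.21 for independent lines) and 1 turned past 1 (2.10 by chance). Of the lower genes 14 kept their direction past 1 (2.38 for independent lines) and 30 turned (3.65 by chance). The numbers for independent lines were thus exceeded in the turning direction too, which makes them a weak baseline. The higher genes go against equal treatment, but it is not excluded. Exchanged labels within the 368T1 pair stay open, because more higher genes kept than turned their direction past 1, while more lower genes turned than kept it. Whether these arrays hold another line cannot be told apart, because 0 of the 2 matched uninfected 368T1 best, which had been set down beforehand as the sign of another line, but their best match, 393T1 (r = 0.39), was also that of an infected 394T4 array (r = 0.46), so the match did not follow the line. Xist argues against 393T1 itself (10.98, against 3.48 and 3.72 in the infected 368T1 arrays) and leaves other Xist-negative lines open. A level already low in the control-infected 368T1 cells may account for the pattern, since it lay at -2.69 relative to the uninfected line, a fall that 172 of 18997 genes matched, but these arrays belong to different runs. A weaker knockdown in 368T1, the biological alternative, was not tested.

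The mesenchymal list was higher in metastasis lines in array runs 3 and 4 (1.22 and 1.30) and not in runs 1 and 2 (-0.36 and -0.09). Run 3 holds 1 metastasis line, 389N1, against 7 primary lines, so its shift rests on that line. A difference between array batches cannot be told apart from one between lines, because 2 of the 4 runs hold lines of 1 number only, and the run as a block, which gave 0.53, removes only shifts in level between runs. Whether lines of a single origin account for the pattern cannot be told apart either. Leaving out the lines of number 482 lowered the shift to 0.26 (adjusted p = 0.149), by just over the margin set down beforehand. It left 1.22 and 0.92 within runs 3 and 4. Leaving out 482N1 with the primary lines 389T2 and 393T5 gave 0.55, which cannot decide this question. Those primary lines had the highest fibroblast marker means of their group, and that list shares genes with the mesenchymal list. A difference between metastasis and primary tumours stays open as the biological explanation, and chance was not excluded for the list calls.

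Line 482N1 had a fibroblast marker mean of 8.25, where the other 8 metastasis lines had 4.76 to 6.16 and the primary lines 389T2 and 393T5 had 7.05 and 6.64. Fibroblasts in the culture are a candidate explanation, since 13 of the 17 markers lay over 1 above the median of the other 8 lines, led by Mfap5 (10.60 against 4.45), Col3a1 (11.40 against 5.94), Postn and Thy1, with Col1a1 at 12.52; Des, Rgs5, Mfap4 and Fbln1 did not. The mesenchymal list holds 10 of the 17 genes, and of the 7 others 3 lay that high. The epithelial junction mean of 482N1 was 6.96, inside the range of the other metastasis lines (5.68 to 7.67), which neither a mixture nor an epithelial line with mesenchymal features excludes. That state of the tumour cells, the biological alternative, cannot be excluded and was not tested.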

How the results depend on the processing

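In this part the list settings for array run, normalisation, left-out lines, list means per line, blocks for the Nkx2-1 level, and the fits without 389T5 or 482N1, were chosen after the result was seen. With 0 clusters called in metastasis against primary lines, none was called under any of its 22 alternatives, including the replicate block over 17 lines of 4 numbers, and unadjusted counts ran from 1598 to 3025, apart from the 177 that also differed by at least 1. The labels do not say whether the line numbers pair the lines. Same-numbered lines correlated at a median of 0.23, and at 0.39 across the groups, against -0.11 for other lines. Of 29 such pairs 7 were negative, and 12 of 19 lines correlated best with their own number. Xist was uniform within each number with several lines, at 3.46 to 4.12 in 373, 389 and 2691 and 10.98 to 12.17 in 393 and 482. This leaves a shared origin of same-numbered lines open. If they share one, tests that take lines as independent can give p-values that are too small. In that replicate block the unadjusted count was 1722, the Nkx2-1 difference was -0.72 (limma, unadjusted p = 0.132), and Hmga2 turned to -0.28; the cause was not tested. It called 6 lists, with the cell cycle (-0.20, adjusted p = 0.0168) in place of the foregut list (mean 0.05, adjusted p = 0.987), and the junction and interferon shifts were -0.32 and -0.15. With an estimated correlation these 6 calls were lost (adjusted p = 0.790). The Nkx2-1 difference lay at -1.64 to -1.06 when the lines of each number were left out (exact p = 0.0191 to 0.0582), above 0.05 in 4 of 9 cases.

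In the knockdown, all 29 arrays in the fit called 3 higher and 5 lower clusters, with a spread estimated from more arrays; its unadjusted count was 1490, and 492 of the 4077 clusters of the planned fit also differed by at least 1. Unadjusted counts were 663 with no replicate block for the pairs, 2799 with the kits averaged, and 2225 to 5363 when a pair was left out, the lowest without the 394T4 Ovation pair. With no replicate block 0 of the 15 genes called over a list alone passed.

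List calls in metastasis against primary lines numbered 10 with the run as a block, 0 with an estimated correlation and 0 by permutation of list means, and 5 to 8 when the lines of a number were left out. In the knockdown they numbered 0 with an estimated correlation, 3 with no replicate block, and 3 to 5 when a pair was left out. Of 494 other list values under an alternative 29 lost and 22 gained a call, and in 29 camera's direction turned, none of them with a call. In metastasis against primary lines it turned, with these means, for the oncofetal list in the replicate block (0.0189) and with the run as a block (0.152), hypoxia after quantile normalisation (0.0119), median centring (0.0934) and 3 left-out numbers (range -0.128 to 0.102), TGF-beta and Wnt after median centring (0.23), RAS and MAPK without 482N1 (-0.0670), without 3 lines (-0.0559) and without 5 numbers (range -0.141 to -0.0424), kidney markers after quantile normalisation (0.0260) and median centring (0.0488), leukocyte markers in the replicate block (0.0357) and without 802T4 (range -0.126 to 0.0682), and the cell cycle without the 393 lines (range -0.33 to 0.0391). In the knockdown it turned for the foregut list with the kits averaged (0.0399) and without the 394T4 Ovation pair (range -0.31 to 0.0520), p53 targets with no replicate block (-0.0194) and without the 394T4 WT pair (range -0.0557 to 0.0510), the cell cycle without the Ovation pair (range -0.0579 to 0.0418), hypoxia without the Ovation or the 368T1 pair (range -0.0466 to 0.106), and fibroblast (range -0.0304 to -0.0053) and mesothelial markers (range 0.0530 to 0.203) without the 368T1 pair. The causes were not tested. Named genes kept their sign in 980 of 981 values, but most were chosen for a small p in these same arrays, which favours a stable sign. The sets of hairpin genes passed in no alternative. Signal over background is not known here, so low clusters are compared as deposited.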

Other observations

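Genes in this part were chosen after their values were seen, and its values belong to no test. Among the 31 genes at least 1 higher in the array labelled shNkx2-1 in all 3 pairs were, besides those named above, Dkk2, a secreted Wnt antagonist (2.43), the pituitary hormone gene Prl (2.46), Lrch2 (2.48), Lmcd1 (2.32), the glutathione transferase Mgst1 (2.10), the growth factor Igf1 (1.48) and the axon guidance receptor Plxna2 (1.19). Among the 14 at least 1 lower were the neutrophil chemokines Cxcl5 (-2.54) and Ppbp (-2.13), the water channel Aqp8 (-2.20) and the glycogen branching enzyme Gbe1 (-2.29). For Cntln 16 of its 17 clusters were higher in all 3 pairs, with a median difference of 1.54 over the clusters.

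In both 394T4 pairs 30 genes were at least 1 lower and in 368T1 at least 1 higher, and 1 gene, Prkd1, ran the other way; the difference between lines was not tested. They included the keratin gene Krt20 (-4.54 and -3.43 in 394T4, 1.31 in 368T1), the actin-bundling protein gene Vil1 (-2.95 and -2.53, against 1.09), Vsig1 (-1.28 and -1.07, against 2.67) and Anxa10 (-2.36 and -1.79, against 1.75). The apolipoprotein gene Apoc2 (-4.73 and -4.57, against 1.02) and Ddc, an enzyme of amine synthesis (-3.56 and -2.83, against 1.56), also ran in opposite directions in the lines.

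Primary line 802T4 had the highest leukocyte marker mean of the 29 arrays, 6.25, with line 373b1 next at 5.10, and the highest antigen presentation mean, 6.68, with 2557T1 next at 5.97. The infected 368T1 cells lay away from the uninfected 368T1 line in more than Nkx2-1: Sftpb read 9.91 in the uninfected line and 4.86 in control-infected cells, Cldn18 11.89 and 7.55, and Hmga2 7.51 and 9.73.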
